A study of Mus musculus with 3 samples.

How the data were processed

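The series holds total RNA of 3 CT26.WT cultures (S100a8, S100a9 and control), each on 1 Affymetrix Mouse Genome 430 2.0 array. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was made from 1 µg of total RNA. The values are the deposited probe set intensities, on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version and its scaling target are not given in the sources used here. The table holds no detection calls and 45101 probe sets in 3 columns, matched to samples by the column names. Its values run from 0.72 to 21962, and the trimmed means of the arrays were 311 (S100a8), 311 (S100a9) and 316 (control). MAS5 subtracts mismatch signal, which makes dim values noisy, and scaling arrays to a common level hides any change in total RNA per cell. Read alignment, genome builds and count models do not apply to these arrays.

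Genes were named from the platform annotation supplied with the table, which can be old. It gave 34958 probe sets 1 gene symbol and 932 several, and it did not list 9160 probe sets that are not controls; the last 2 kinds were left out of gene values. Of the probe sets with 1 symbol, 34754 were matched by their Entrez number to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names only, and no coordinates are given. Some genes of the lists had no probe set with a single symbol and are not reported here. The 64 AFFX control probe sets were used only for quality.

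Deposited intensities were kept at their scale. Values under the floor, the 50th percentile of all values of the 3 arrays (76.0), were set to the floor and log2 was taken. Each of 18194 named genes was represented by its probe set with the highest mean log2 intensity, and a gene was compared if that mean lay above the floor, which left 11138. The log2 ratios and folds were computed here from the deposited signals, and a fold against a value at the floor is given as a lower bound. That bound allows for the cut at the floor, not for the noise of dim signals. The comparisons were S100a8 against control, S100a9 against control and S100a9 against S100a8, with counts of genes at least 2-fold higher or lower as a descriptive size. Groups came from the labelled agent. With 1 array per group there was no test and no p-value.

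The genes named in the text followed a rule set before the data were examined. It took, against control, the 10 highest and 10 lowest ratios above the floor on both arrays, and between the proteins the first 5 of each. A gene was passed over if another of its probe sets above the floor went the other way. The rule added the first 3 per direction with 1 array at the floor, up to 4 members per described list (the 2 highest and 2 lowest ratios in any comparison), 5 genes per direction shared by both proteins, and S100a8, S100a9, Ager, Tlr4, Bsg, Cd36, Id3, Smad5 and Akt1. Clone or model names were passed over 9 times.

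In addition, 32 gene lists were fixed before the data were examined. They covered signalling targets, cell cycle, metabolism, stress, protein turnover, the S100 family and its receptors, and markers of other cell types. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. It was called apart below the 2.5th or above the 97.5th percentile, which about 5% of lists of randomly drawn genes would reach. Genes of a real list can vary together between cultures, which this rate leaves out. Lists with fewer than 5 compared members got values only, which left 30. The likeness of the 2 proteins was set beside 100 simulations of unchanged arrays sharing a control, with noise by intensity taken from the S100a9 against S100a8 differences.

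Array quality was read from the spike-in controls. The 18 hybridization spike-ins had median log2 ratios of 0.02 (SD 0.04) for S100a8 and −0.01 (SD 0.08) for S100a9 against control. The 24 poly-A spike-ins, added before labelling, had 0.12 (SD 0.12) and 0.28 (SD 0.10). For S100a9 against S100a8 they had 0.19 (SD 0.16). The 3′ to 5′ ratio of Gapdh was 1.01, 1.03 and 0.96 on the S100a8, S100a9 and control arrays, and that of Actb 1.65, 1.56 and 1.44.

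The scripts were tested on simulated data for S100a8 against control over 11166 genes. Of 100 genes raised and 100 lowered by 1.5 on the log2 scale, 99.0% and 83.0% were found at least 2-fold apart, as was 1 unchanged gene. A list shifted by −0.3 had a median of −0.33, and 9 of 200 unchanged lists (4.5%) were called apart. The simulated genes varied independently, so this rate does not cover lists whose members vary together. Alternatives were median centring, quantile normalization, floors at the 30th and 65th percentiles, no floor with log2(value + 1), no filter, the mean of all probe sets, probe sets without _x_at or _s_at endings first, and a 1.5-fold size. Centring by brightness in 20 bins and keeping only genes above the 75th percentile were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.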

Results

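CT26.WT is a mouse colon carcinoma cell line. S100a8 and S100a9 are small calcium-binding proteins that myeloid cells release at sites of inflammation, and Tlr4 and Ager are among their described receptors. The study measured how the transcriptome of these tumour cells differed after exposure to either recombinant mouse protein. Per the labels, cells were held without serum for 12 h and then received 4 µg/ml of S100a8 or S100a9 for a further 24 h. The sample annotation used here records the 24 h only for the protein-treated cultures, with no such time for the control. RNA from each culture was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, so the S100a8, S100a9 and control groups each held 1 array. The control's own labels differ: its title names bovine serum albumin, while its description and the series design name saline. There were no replicates, so no test was possible. Differences are given as log2 ratios or fold sizes between single arrays, and the number of arrays limits the precision of every value. The median signal was 78.6 on the S100a8 array, 73.6 on the S100a9 array and 76.1 on the control array. A gene was compared when its brightest probe set had a mean above the floor, the median of all signals (76.0), and 11138 named genes met this.

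The cells carried transcripts of some described receptors, while the genes of the added proteins themselves lay below the floor. Tlr4, the endotoxin receptor, had signals of 365 with S100a8, 404 with S100a9 and 381 in the control, and Bsg (basigin) had 1994, 2228 and 2198. Ager, the receptor for advanced glycation end products, lay below the floor on each array (63.2, 61.1 and 72.0), as did Cd36, a scavenger receptor (59.7, 38.9 and 43.4). The S100a8 gene gave signals of 14.7, 13.5 and 13.5 and the S100a9 gene 38.5, 24.2 and 37.1. Smad5, a BMP signal transducer, had 892, 885 and 889, and the kinase gene Akt1 had 1084, 1071 and 881. Of the 17 genes listed as S100A8/A9 receptors and proximal signalling, 13 were compared, and their median log2 ratio was −0.06 for S100a8 and 0.01 for S100a9. Ly96, which encodes the partner of Tlr4 at the cell surface, had log2 ratios of −0.88 and −0.70.

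The S100a8-treated cells had lower signals than control for inflammatory chemokine and NF-kB target genes, for interferon-stimulated genes and for cholesterol synthesis genes. Ccl2, which attracts monocytes, was 3.87-fold lower (signals of 576 with S100a8 and 2227 in the control). The neutrophil attractant Cxcl3 was 3.36-fold lower, the T cell attractant Cxcl10 3.24-fold lower and Ccl20 2.86-fold lower. Genes of the Id family of transcription inhibitors were higher, with Id3 2.27-fold above control. In all, 32 genes were at least 2-fold lower and 5 at least 2-fold higher.

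Of the 35 listed NF-kB inflammatory targets, 24 were compared in S100a8-treated cells and 23 were lower, 18 of them by at least 1.5-fold. The list's median log2 ratio was −0.88, and 0 of 10000 random lists matched on mean expression had a median as low. Ccl2 (−1.95) and Cxcl10 (−1.69) had the lowest ratios above the floor. Nfkbie, an inhibitor of NF-kB that is itself an NF-kB target, was 3.06-fold lower. Lcn2, an iron-carrier binding protein, was the 1 member above control (0.48), and the T cell chemokine gene Ccl5 had a log2 ratio of −0.08.

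All 30 compared interferon-stimulated genes were below control in S100a8-treated cells, 16 by at least 1.5-fold. The median log2 ratio was −0.70, and 0 of 10000 random lists were as low. Parp14, an ADP-ribosyltransferase, was 2.71-fold lower, and Rsad2, the antiviral protein viperin, had a log2 ratio of −1.26. The smallest differences were those of Cmpk2 (−0.01) and Ifit2 (−0.06). Gbp6, an interferon-inducible GTPase outside the list, was at least 2.06-fold lower, since its signal on the S100a8 array lay below the floor. Antigen presentation genes had a median of −0.25, with 12 of 15 lower. Among them were Cd274, the immune checkpoint ligand PD-L1 (−0.99), and Nlrc5, a regulator of MHC class I genes (−0.46), while Erap1 was at 0.10. Oas1e, by name a member of the interferon-induced oligoadenylate synthetase family, went the other way. It was 3.86-fold higher, from a dim control signal of 89.1 to 344, on a single probe set.

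Each of the 20 compared cholesterol synthesis genes was below control with S100a8, with a median log2 ratio of −0.39 (0 of 10000 random lists as low). Lss, lanosterol synthase, was at −0.73 and Pmvk, phosphomevalonate kinase, at −0.65. The values nearest to control were those of Sqle, squalene epoxidase (−0.06), and Msmo1 (−0.28).

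Immediate-early and MAPK feedback genes had a median of −0.22 with S100a8, with 23 of 29 lower. Fos was at −1.18 and Egr1 at −0.92, and the feedback inhibitor Spry2 was at 0.31. The p53 targets had a median of −0.20 (17 of 21 lower), led by Ddit4, an inhibitor of mTORC1 (−0.72), and Btg2, an antiproliferative gene (−0.63). Ptp4a3 (0.27) and Ei24 (0.20) were highest. The median of the FOXO and serum withdrawal genes was −0.22 (10 of 15 lower), with Foxo3 at −0.47 and Bcl6 at −0.41, against Foxo1 at 0.34. Smaller medians lay below the random range for the ATF4 and amino acid response genes (−0.09) and for the G2/M and mitosis genes (−0.10; 18 of 29 lower). The mitotic list kept its call under 7 of 10 alternative settings, the ATF4 list under 8 and the FOXO list under 9. The FOXO median ranged from −0.31 to −0.06 over these settings.

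The TGF-beta/BMP-SMAD targets did not move as 1 group with S100a8. Id3 (1.18) and Id1 (0.77), which inhibit helix-loop-helix transcription factors, were higher, as was Id2 (0.59). In contrast, 13 of the 23 compared members were lower, among them Inhba, the activin beta A subunit (−0.97), and Skil, a SMAD corepressor (−0.57). The median of −0.13 lay below the central 95% of random lists, a call kept under 8 of 10 alternatives.

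Fibroblast markers had a median log2 ratio of −0.49 with S100a8. Here 6 of 11 listed genes were compared and all 6 were lower. For the fibroblast markers, the median was −0.28 with the floor at the 30th percentile, −0.27 with the mean of all probe sets and −0.02 without the filter on dim genes, each below the random range. Pdgfrb, a platelet-derived growth factor receptor, and the matrix proteoglycan decorin, Dcn, were both at −0.92, while Col1a2 was at −0.02. Matrix protease genes as a list stayed inside the random range (median −0.09), but several metalloproteinases were among the lowest genes. Mmp13, a collagenase, was at least 3.44-fold lower, and the stromelysins Mmp10 (−1.39) and Mmp3 (−1.31) were also low. Mmp9, a gelatinase, was at 0.58 and the protease inhibitor Timp1 at 0.35.

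Other genes with large negative ratios under S100a8 were Cyp26b1, which degrades retinoic acid (2.91-fold lower), Acod1, which makes itaconate (2.77-fold), and Hes1, a Notch-responsive repressor (2.65-fold). The homeobox gene Dlx2 was at least 1.95-fold lower. The 5 genes at least 2-fold higher were Oas1e, Serpinb9b, Id3, Klk10 and 2610020C07Rik, of which the clone-named gene was named after its value was seen. Serpinb9b, a serine protease inhibitor of clade B, was 2.58-fold higher (923 against 358), and Klk10, a kallikrein-related protease, 2.07-fold. Next came Sdc1, the heparan sulphate proteoglycan syndecan-1 (1.95-fold), Plb1, a phospholipase (1.95-fold), and Suox, sulphite oxidase (1.88-fold). Dynap (1.88-fold), Eno4 (1.87-fold) and the fetal plasma protein gene Afp (1.79-fold) followed. Kcnab3, a potassium channel subunit, was at least 1.78-fold higher, Hamp2, a hepcidin, at least 1.57-fold and the transcription factor gene Foxp2 at least 1.57-fold.

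Lists above the random range with S100a8 had medians between 0.06 and 0.41. The NRF2 and redox genes were at 0.15 (16 of 18 higher), with Srxn1, sulfiredoxin, at 0.57 and Taldo1 at 0.46, against Tkt at −0.12. Oxidative phosphorylation genes were at 0.07 (27 of 37 higher, a call kept under 9 of 10 alternatives), proteasome genes at 0.06 (24 of 31 higher) and S100 family genes at 0.13 (7 of 7 higher, a call kept under 6 of 10 alternatives). Macrophage and granulocyte markers were at 0.41, with 8 of 8 compared members higher, including Cd68 (0.62) and Cd53 (0.48), a call kept under 7 of 8 alternatives. Lymphoid and endothelial markers, with 3 compared members each and too few for a percentile, were of similar size, with medians of 0.36 and 0.27 and 3 of 3 members higher in each. The lymphoid genes Cd3e, Cd4 and Cd8a were at 0.15, 0.36 and 0.39 with S100a8 and at −0.16, 0.01 and 0.23 with S100a9. The endothelial genes Kdr, Egfl7 and Esam were at 0.10, 0.27 and 0.43 with S100a8 and at −0.06, 0.003 and 0.23 with S100a9. This array also had raised dim signals: the dimmest 25% of compared genes had a median log2 ratio of 0.14, against −0.01 for the rest. Of 78 olfactory and vomeronasal receptor probe sets, a panel chosen as likely silent in these cells, 9 (11.5%) were above the floor on the S100a8 array and 5 (6.4%) on the control array. With the floor at the 65th percentile, 3 genes in place of 5 were at least 2-fold higher.

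The S100a9-treated cells also had lower signals than control for chemokine genes. Cxcl10 was 2.84-fold lower (604 against 1715), Ccl2 2.74-fold and Ccl20 2.51-fold lower. NF-kB targets, interferon-stimulated genes and cholesterol synthesis genes were again below control. Serpinb9b had a log2 ratio of 1.32 and Id3 of 0.96. Here 16 genes were at least 2-fold lower, 13 of which were so with S100a8 too, and Serpinb9b was the 1 gene at least 2-fold higher.

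With S100a9, 22 of 24 compared NF-kB targets were lower, 17 by at least 1.5-fold, and the median log2 ratio was −0.77 (0 of 10000 random lists as low). Nfkbie had a log2 ratio of −1.32. Cxcl3 (2.49-fold) and Cxcl5 (2.10-fold), which both attract neutrophils, were also lower, while Lcn2 was at 0.48 and Ccl5 at 0.13. Of 30 interferon-stimulated genes 26 were lower, 5 by at least 1.5-fold, with a median of −0.36 (0 of 10000 as low). Rsad2 was 2.07-fold lower and Parp14 was at −0.78, whereas the cytosolic RNA sensor regulator Dhx58 (0.16) and the transcription factor gene Irf7 (0.08) were not below control. Antigen presentation genes had a median of −0.13 (12 of 15 lower), with Cd274 at −0.77 and H2-K1, an MHC class I heavy chain, at −0.30.

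Cholesterol synthesis genes had a median of −0.20 with S100a9, and 19 of 20 were lower (0 of 10000 random lists as low). Lss was at −0.51 and Insig1, a sterol-responsive regulator, at −0.34, and Sqle was at 0.01. The p53 targets were at −0.20 (16 of 21 lower), with Ddit4 at −0.64 and Btg2 at −0.37. Immediate-early and MAPK feedback genes were at −0.14 (18 of 29 lower), with Egr1 at −0.66 and Ereg, an EGF receptor ligand, at −0.62. The FOXO and serum withdrawal genes stayed inside the random range (−0.04). Medians also lay below the range for the TGF-beta/BMP-SMAD targets (−0.10), G2/M and mitosis genes (−0.08; 22 of 29 lower), ATF4 and amino acid response genes (−0.07), ER chaperone genes (−0.07) and fibroblast markers (−0.17; 5 of 6 lower). Each of these 5 calls except that of the mitotic list was lost under 1 alternative. Among the SMAD targets, Inhba was at −0.74 and Junb at −0.51, against Id3 at 0.96 and Id1 at 0.57.

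Outside these lists, Mmp13 was 2.49-fold lower with S100a9, Cyp26b1 2.30-fold and the matrix proteoglycan gene Ogn, osteoglycin, 2.09-fold. Rph3a, a vesicle trafficking gene, was at least 2.04-fold lower, the growth hormone gene Gh at least 1.53-fold and Zfp229 at least 1.45-fold. Higher genes included Dynap (1.81-fold), Dlk2, a transmembrane EGF-repeat protein (1.75-fold), Htra1, a secreted serine protease (1.66-fold), and the growth factor gene Pdgfc (1.63-fold). Sqor, which oxidises sulphide in mitochondria, was 1.60-fold higher, Sbsn 1.59-fold, Tmem117 1.59-fold and Klk10 1.58-fold. Tcam1 was at least 1.62-fold higher, the prolactin gene Prl at least 1.51-fold and Kcnab3 at least 1.47-fold. Genes given here as at least a fold had 1 array at the floor, where signals are noisy. With S100a9, 6 of 78 likely silent receptor probe sets (7.7%) lay above the floor. The NRF2 and redox genes had a median of 0.11 (14 of 18 higher), with Blvrb, biliverdin reductase B, at 0.47 and the cystine transporter gene Slc7a11 at 0.41. Oxidative phosphorylation genes were at 0.07 (29 of 37 higher), S100 family genes at 0.13 (7 of 7), macrophage and granulocyte markers at 0.18 (5 of 8) and E2F and DNA replication genes at 0.06 (19 of 30). The S100 family median ranged from 0.006 to 0.171 over the 10 alternatives, with its call kept in each. The E2F call was kept under 7 of 10 alternatives and the macrophage call under 5 of 8, and with the floor at the 30th percentile 3 genes were at least 2-fold higher.

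**Figure D1:**
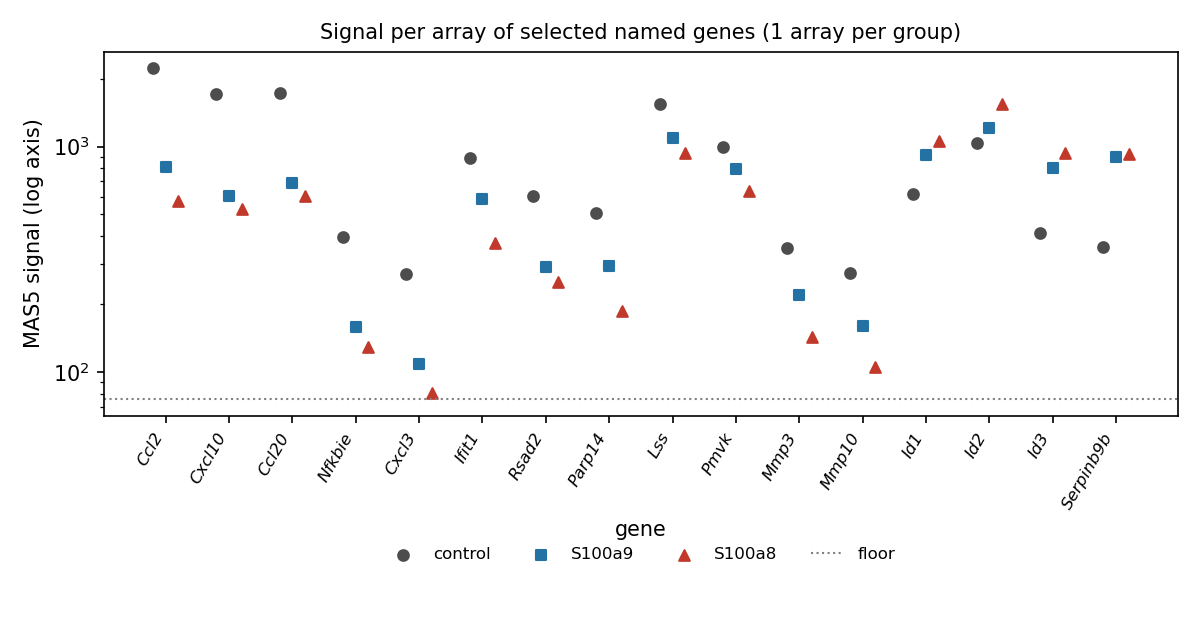
MAS5 signal (log axis) of 16 genes named by the rule fixed beforehand, with 1 point per array (control, S100a9, S100a8) and a dotted line at the floor. Ccl2, with signals of 2227, 813 and 576, and the 11 other genes from Cxcl10 to Mmp10 were highest in the control, while Id1, Id2, Id3 and Serpinb9b were lowest there.

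Many of the genes with the lowest signals relative to control were the same with either protein. Of the genes at least 2-fold lower, 13 were lower under both proteins: Acod1, Bdkrb2, Ccl2, Ccl20, Cxcl10, Cxcl3, Cyp26b1, Lif, Mmp13, Nfkbie, Ogn, Rsad2 and Tnfaip3, some of them outside the naming rule and named after their values were seen. Serpinb9b was the 1 gene at least 2-fold higher under both, and 0 genes passed this size in opposite directions. After Serpinb9b and Id3, the largest shared increases were those of Dynap (1.81-fold), Dlk2 (1.70-fold) and Htra1 (1.66-fold), each under the protein with the smaller ratio.

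Both ratios used the same control array, which makes them alike even without an effect. Over genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.66, against 0.50 on average in simulated unchanged arrays sharing a control. The equal noise given to the simulated arrays sets that 0.50 by itself. Spearman's rho was 0.59. The covariance was 0.0324, against 0.0165 simulated, a difference of 0.0159. By construction the covariance equals the variance particular to the control array (0.0324), which pools that array's noise with any shared effect. The variance particular to the S100a8 array was of the same size (0.0328) and that of the S100a9 array was 0.0045, while the simulation took the arrays to be equally noisy. Independent lists would share 0.046 lower and 0.0004 higher genes, and simulated unchanged arrays shared 0.0 lower and 0.01 higher genes. The simulated counts follow from noise drawn for each gene alone and equal across arrays. They do not cover genes that vary together between cultures. The control could not be split, so part or all of the excess may come from it. Where genes had more than 1 probe set above the floor, the log2 ratios of a pair of them correlated at r = 0.42 over 4948 genes for S100a8 and 0.41 for S100a9. The further probe set went the same way for 7 of 11 genes at least 2-fold from control with S100a8 and for 4 of 7 with S100a9. Bdkrb2 and Lif, both among the 13 shared genes, were not borne out by it.

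**Figure D2:**
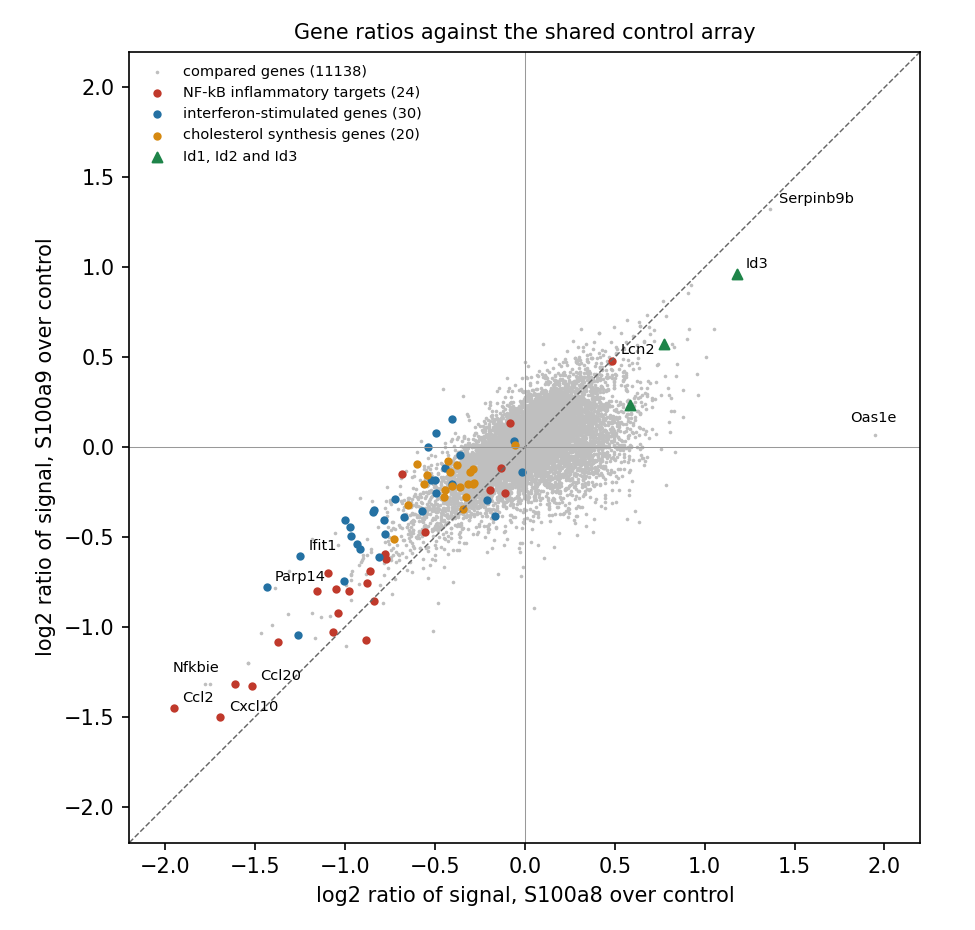
Log2 ratio of signal over control for S100a8 (x axis) and S100a9 (y axis), with 1 grey point for each of 11138 compared genes and coloured points for 3 gene lists and the Id genes. The dashed line marks equal ratios. NF-kB targets (medians −0.88 and −0.77; 19 of 24 above it) and interferon-stimulated genes (−0.70 and −0.36; 27 of 30) lie mostly above it, closer to control with S100a9. The interferon-stimulated genes lie further from the line.

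Set against each other, the S100a9-treated cells had higher signals than the S100a8-treated cells for interferon-stimulated and cholesterol synthesis genes. The ratios of this comparison leave out the control array's signals, but the floor, the filter and the probe set choice used all 3 arrays. Ifi207, an interferon-inducible gene of the p200 family, was 1.72-fold higher with S100a9, Parp14 1.58-fold and Ifit1, an interferon-induced RNA-binding protein, 1.56-fold. Fos was 1.59-fold higher and decorin, Dcn, 1.55-fold. At the 2-fold size, 0 genes were higher and 2 lower, Oas1e (3.68-fold lower) and the immunoglobulin gene Ighg3 (2.07-fold lower).

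The interferon-stimulated genes had a median log2 ratio of 0.34 for S100a9 over S100a8, with 27 of 30 higher. All 20 cholesterol synthesis genes were higher, with a median of 0.18, among them Tm7sf2 (0.51) and Mvd (0.39). NF-kB targets were at 0.18 (19 of 24 higher), with Saa3, an acute-phase protein, at 0.53 and Ccl2 at 0.50, against Cxcl5 at −0.19. In these 3 lists 0 of 10000 random lists had a median as high. FOXO and serum withdrawal genes (0.17) and fibroblast markers (0.19) also lay above the random range, and each call was lost under 1 alternative. Over the alternatives their medians fell as low as −0.02 and 0.0. The NRF2 and redox genes (−0.05) and the Wnt/beta-catenin targets (−0.09) lay below it, and the Wnt call was kept under 4 of 10 alternatives. Axin2, a feedback inhibitor of Wnt signalling, was at −0.56. The poly-A spike-ins had a median log2 ratio of 0.19 (SD 0.16) for S100a9 over S100a8, against 0.02 over all compared genes. The cholesterol, NF-kB, FOXO and fibroblast medians were of about that spike-in size, which limits what they show.

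Among other genes lower with S100a9 than with S100a8 were Pltp, a phospholipid transfer protein (2.00-fold), Zfp982 (1.96-fold) and Hoxc9 (1.96-fold). At least 1.70-fold, 1.66-fold and 1.65-fold lower were Col9a1, Gnao1 and Gh. Gbp6 was at least 1.41-fold higher, Iglon5 at least 1.39-fold and Akr1c14 at least 1.39-fold. Their signals on the S100a9 array ran from 67.0 (Gh) to 151 (Pltp), and the dimmest 25% of genes had a median of −0.12 in this comparison, against 0.04 for the rest. The count of 2 lower genes was 5 with the floor at the 30th percentile and 0 at the 65th.

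**Figure D3:**
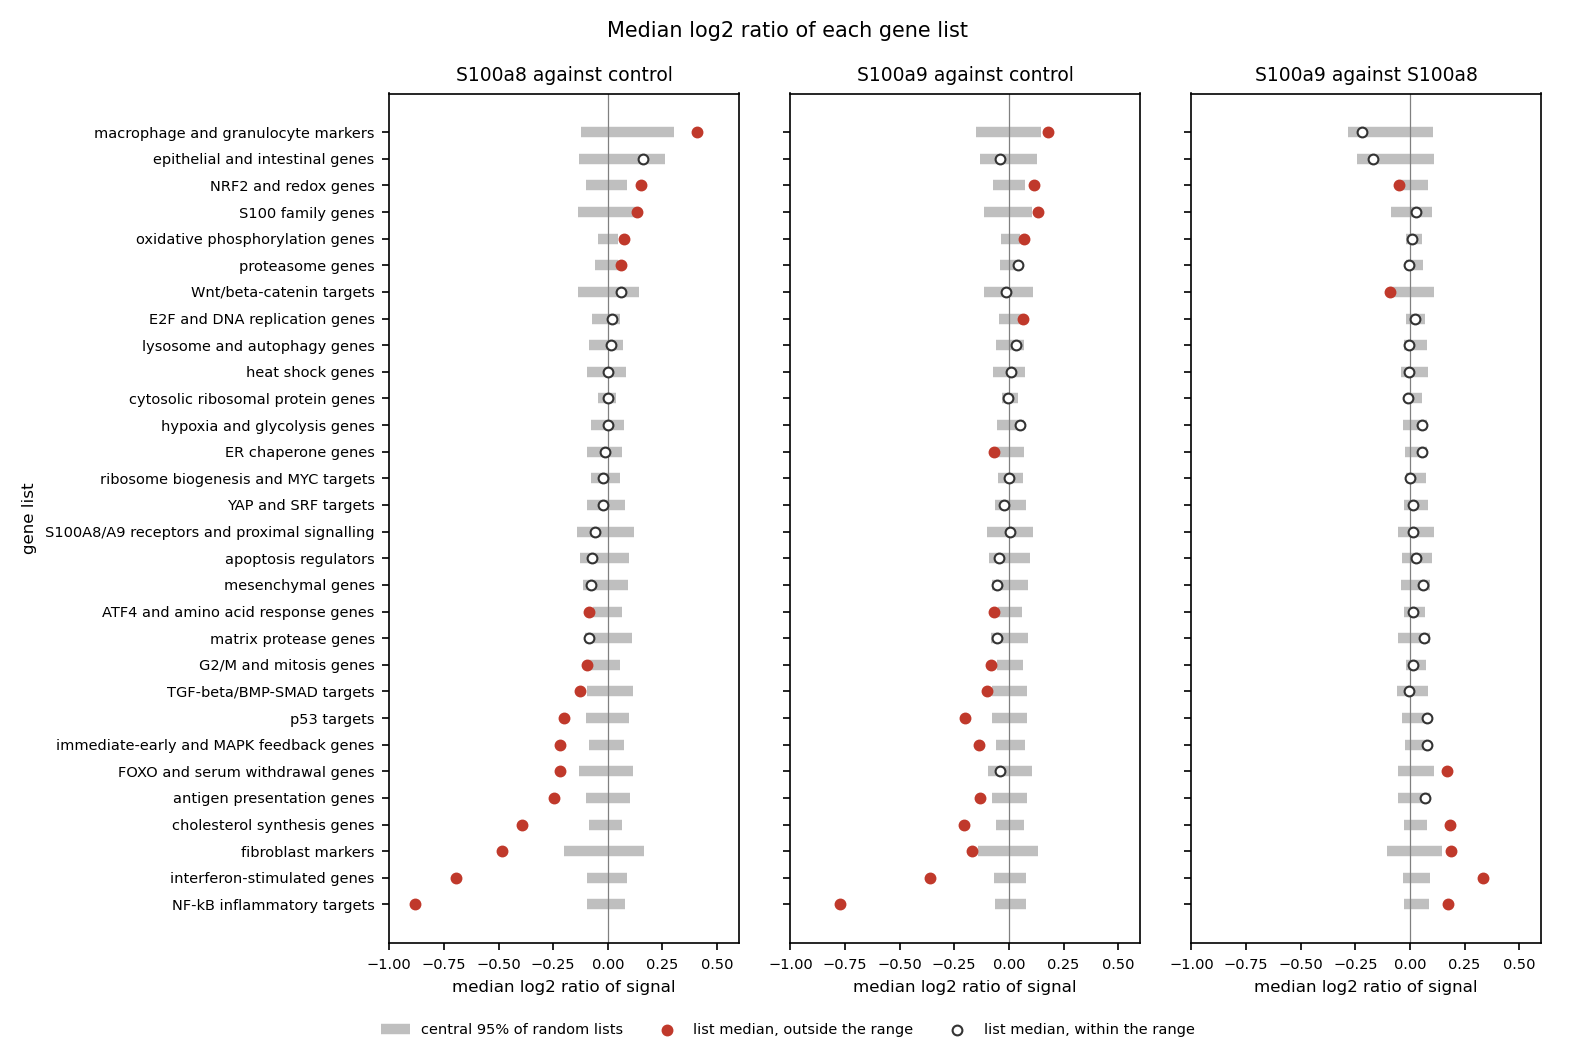
Median log2 ratio of signal of each of 30 gene lists (points) in the 3 comparisons, with grey bars for the central 95% of 10000 random lists matched on mean expression. Filled points lie outside the bars: 16 lists for S100a8 against control, 16 for S100a9 against control and 7 for S100a9 against S100a8. Lists of randomly drawn genes would give 1.5, which is no rate for real lists, whose members can vary together between cultures.

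Several gene lists did not stand apart with either protein, which does not mean that each of their members stayed near control. The range can be wide: for the 9 compared epithelial and intestinal genes it ran from −0.13 to 0.26 with S100a8. For S100a8 and S100a9 in turn, medians inside the random range were 0.06 and −0.01 for the Wnt/beta-catenin targets, −0.08 and −0.05 for mesenchymal genes, and 0.16 and −0.04 for epithelial and intestinal genes. Hypoxia and glycolysis genes were at −0.001 and 0.05, heat shock genes at 0.003 and 0.01, and lysosome and autophagy genes at 0.02 and 0.03. Cytosolic ribosomal protein genes were at 0.0 and −0.01, and ribosome biogenesis and MYC targets at −0.02 and 0.0. YAP and SRF targets were at −0.02 and −0.02, apoptosis regulators at −0.07 and −0.05, and matrix protease genes at −0.09 and −0.05. Inside the range with 1 protein were E2F and DNA replication genes (0.02) and ER chaperone genes (−0.01) with S100a8, and proteasome genes (0.04) with S100a9. With the mean of all probe sets in place of the brightest, the lysosome list with S100a8 (−0.10) and the mesenchymal list with S100a9 (−0.10) lay below the random range.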

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

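The tests of the ribosomal RNA signals were chosen only after the result was seen. Control probe sets for 18S ribosomal RNA, which no comparison used, were brighter on both protein arrays than on the control array. The 3′ probe set was 2.75-fold brighter with S100a8 and 2.87-fold with S100a9, the middle one 2.22-fold and 2.32-fold, and the 5′ one 1.44-fold and 1.39-fold. An array-wide hybridization difference is argued against by the hybridization spike-ins, with a median log2 ratio of 0.019 for S100a8. The poly-A spike-ins, added before labelling, were higher on both protein arrays, with medians of 0.12 for S100a8 and 0.28 for S100a9. The medians of the 18S probe sets were larger, at 1.15 and 1.22. A loss of 5′ signal in messenger RNA is argued against as the whole cause by the Gapdh 3′ to 5′ ratios, 1.048-fold apart; those of Actb differed in the same direction as 18S, by 1.145-fold (1.65 with S100a8 and 1.44 in the control). More ribosomal RNA carried into the labelled material of both treated samples, or a control sample prepared apart from them, may account for it; no biological explanation was tested.

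Some probe sets without a gene name here were also at least 2-fold from control. Of 3017 above the floor, 5 were at least 2-fold higher with S100a8 and 2 with S100a9. Lower ones were more frequent, at 62 (2.06%) with S100a8 and 19 (0.63%) with S100a9. Among 19410 named probe sets above the floor, 0.41% and 0.20% were at least 2-fold lower. These shares were not matched on brightness.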

How the results depend on the processing

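The settings centred by brightness and restricted to genes above the 75th percentile were chosen only after the data were seen. No paired analysis was possible because each group held 1 array. At a 1.5-fold size the counts of higher and lower genes were 126 and 213 for S100a8, 28 and 95 for S100a9, and 11 and 112 for S100a9 against S100a8, with 76 lower and 19 higher under both proteins. The share of lower genes then was 62.8%, 77.2% and 91.1%, against 86.5%, 94.1% and 100.0% at 2-fold. With the floor at the 30th percentile, 3 genes were higher with S100a9 and 5 were lower with S100a9 than with S100a8. With the floor at the 65th percentile, 3 genes were higher with S100a8 and 0 were lower with S100a9 than with S100a8. Among genes above the 75th percentile, which leaves fewer genes, 3 were higher and 15 lower with S100a8, 9 lower with S100a9 and 0 lower between the proteins. In that set 7 were lower under both proteins and r was 0.785. Beyond these construction effects the cause was not tested. Other counts stayed within 1.5 times their value, and no count reversed its balance of higher and lower genes. Of the 32 genes lower with S100a8, 25 remained with the floor at the 65th percentile, 26 with the mean of all probe sets and 30 under quantile normalization.

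The NF-kB, interferon and cholesterol lists stood apart in each comparison under all 10 alternatives. The NF-kB median ranged from −0.89 to −0.73 for S100a8 and from −0.80 to −0.54 for S100a9, the interferon median from −0.78 to −0.55 and from −0.40 to −0.35. For S100a9 against S100a8 the NF-kB median ranged from 0.06 to 0.174 and the interferon median from 0.297 to 0.335. Over all lists and alternatives, 843 medians kept their side of the bounds, 32 moved inside and 10 outside. The macrophage medians were 0.0 without the filter on dim genes, where most members sit at the floor. Of the log2 ratios of named genes under alternatives, 597 lay within 1 SD of the poly-A spike-in ratios from the reported value and 40 did not, Foxp2, Gh and Kcnab3 most often; none changed sign. Dim signal limits the precision: 2-fold ratios near the floor of 76.0 rest on small signal differences.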

Other observations

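The tests of array scaling, of macrophage RNA, of BMP targets and of the contrast between interferon and NF-kB genes were chosen only after the result was seen. Some genes differed from control inside lists whose medians lay inside the random range. Among apoptosis regulators, Bcl2l11, which encodes the death activator Bim, had log2 ratios of −0.90 with S100a8 and −0.60 with S100a9, and the initiator caspase gene Casp8 had −0.46 and −0.38. Bik, another death activator of the Bcl2 family, was at 0.56 and 0.39. Among mesenchymal genes, the collagen genes Col6a1 (−0.97 and −0.71) and Col5a1 (−0.70 and −0.63) were below control, while Sparc, a matrix glycoprotein, was above it (0.28 and 0.37). Sqstm1, the autophagy receptor p62, was at −0.57 and −0.53, and Zyx, the focal adhesion protein zyxin, at −0.58 and −0.48.

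Of 24 listed epithelial and intestinal genes, 15 lay below the filter and 9 were compared, while 11138 of all 18194 named genes were compared. Lying below the filter does not show that a gene was silent, since Gapdh and Rps16 lay below it too. Among the 9, Krt18 was at −0.49 with S100a8. The tight junction gene Cldn3 was at 0.48 with S100a8 and −0.31 with S100a9.

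NF-kB and interferon genes were lower on both protein arrays. Array scaling or an intensity trend would shift genes of similar brightness alike. With S100a8, the lowest median log2 ratio of any brightness bin was −0.05, against −0.88 for the NF-kB list. This argues against either as the whole cause for the NF-kB genes with S100a8. Centring by brightness left the NF-kB median at −0.855, below the random bound of −0.09. That result is no separate evidence, since the random lists were already matched on mean expression. Noise of single probe sets is argued against by the further probe sets of these genes, of which 30 of 34 (88.2%) were lower with S100a8 and 32 with S100a9. The state of the control culture stays open, as it moves both ratios alike and there was 1 control array. Its vehicle is labelled both as albumin and as saline, and its ribosomal RNA signal stood apart from both treated arrays, so the shared part of the pattern could lie in the control. An effect of the S100 proteins, which the design names, stays open beside it, and only the ratios between the proteins leave out the control array's signals.

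Macrophage and granulocyte markers were higher on the S100a8 array, where 8 of 18 listed genes were compared, and Fcer1g passed the filter only through its S100a8 signal (98.9, against 74.1 with S100a9 and 72.3 in the control). Raised dim signal on that array stays open as a cause: centring by brightness cut the median from 0.41 to 0.229, above the random bound of 0.19 by less than the SD over members (0.195), and without the filter on dim genes it was 0.0. Lymphoid (0.36) and endothelial markers (0.27) were also higher there, with 3 of 3 genes each, and more of the likely silent receptor probe sets lay above the floor (11.5%, against 6.4% in the control). Macrophages or their RNA stay open as well. Of 6 abundant macrophage genes, Lyz2, Fcer1g and Ctss lay above the floor on the S100a8 array and all 3 were higher than control. Choosing genes by that array favours higher ones, so this count cannot decide. Fcer1g, below the floor in the control, could only come out higher. Tyrobp, C1qa and C1qb lay below the floor on the S100a8 array and show no direction. Tests that asked for a 2-fold gain, counted genes below the floor, or set these signals against that of Cd68 were dropped as unsuited.

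Id1, Id2 and Id3 were higher with both proteins. A broad rise of BMP-SMAD targets was one hypothesis. The median log2 ratio of 8 other BMP-SMAD targets was 0.127 with S100a8 (SD 0.34; range −0.68 to 0.51; 6 of 8 higher), which lies below the smallest Id ratio of 0.59 by more than that SD. With S100a9 it was −0.09 (3 of 8 higher). The Id genes were singled out as the highest members of the SMAD list with S100a8. A lower median of the other targets was therefore partly built in, and the result cannot decide. With S100a9, Atoh8, one of these targets, was at 0.54, above Id2 at 0.23. Other targets, such as Smad6 and Bambi, lay below the filter. As a group the compared targets had smaller ratios than the Id genes with S100a8, and a smaller increase stays open.

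The interferon genes differed more between the proteins than the NF-kB genes did. The difference of the list medians for S100a9 against S100a8 was 0.161, while the central 95% of matched random lists ran from −0.08 to 0.08, and 1 of 10000 pairs was as high. This describes the arrays compared. With 1 culture per protein, a different response to the proteins by gene group cannot be told apart from a difference between cultures.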
